A study of Mus musculus with 24 samples.

How the data were processed

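Poly(A)-based RNA sequencing of the hippocampus was analysed for 24 libraries in 5 groups: nonstressed mice on the control diet (n = 4), and stressed mice given sham treatment or electroconvulsive therapy (ECT) on the control diet (n = 5 and n = 6) or on the PLX diet (n = 5 and n = 4). Each library was assigned to its group from its own title. The labels describe the subjects as mice, but do not state that each library came from a separate mouse, so the p-values measure the spread between these libraries. Titles also carry a letter shared by some libraries of a group, whose meaning is not given in the sources used here. The consensus correlation within a letter was estimated at 0.189. The main fit and the list tests treat libraries that share a letter as independent, which may understate the spread.

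The deposited table holds one signal column per library, headed as normalized counts per the file headers: reads per gene divided by a size factor of that library. Per the submitters' processing notes, the tools were cutadapt, TopHat2 2.0.10, HTSeq 0.6.1p1 and DESeq2 1.6.3. The notes name the builds mm10 and hg19 without a role for either. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes on opposite strands could not be told apart, and near-identical gene copies are uncertain. Within each column the values were whole multiples of a single step. Dividing by that step gave whole reads for 100% of the values in every library (tolerance 0.001 reads), with 14.97 M to 20.12 M reads per library and size factors of 0.917 to 1.205. A count of 3 reads corresponds to 0.149 to 0.2004 CPM in these libraries, and limits of this kind cover counting error only. The 47 pairs of replicates differed by more than sampling noise (chi-square per degree of freedom 3.64 to 26.3) and correlated at 0.974 to 0.994 on the log2 scale across genes, so no library was treated as a repeat of another.

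The planned test was edgeR's quasi-likelihood test on counts, with a stated fallback for normalized values. Because the table holds normalized values, the fallback was used: limma 3.58.1 with trend and robust options on log2(value + 1), for the 15225 of 23240 genes with a value of at least 10 in at least 4 libraries. One model with 5 group means was fitted to all 24 libraries, and 7 comparisons were drawn from it. P-values were adjusted by the Benjamini-Hochberg method over all tested genes within a comparison, and genes with an adjusted p below 0.05 were called. Some counts of genes at an unadjusted p below 0.05 stand beside the number that chance gives on average. Genes vary together across libraries, so such counts can scatter widely around that number, and no surplus is read from them. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Values are normalized read counts, given as mean ± SD.

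Of 36 gene lists fixed in advance, 33 were tested with camera (limma, 2-sided, preset correlation of 0.01), adjusted over the 33 lists. Each was also tested with a correlation estimated from the data, with fry for movement in one direction or in either direction, and with an exact permutation test of the mean of its members, 2-sided, for comparisons of 2 groups. The mitochondrial list had 0 of 13 members in the table used here, the blood list 1 tested member and the list of other leukocytes 2, and these were not tested. The preset correlation is far below the correlations estimated in these libraries, so most list results of the main fit are given with both. Lists that did not pass, and most list results of other fits, are given with the preset one only. List members were also adjusted over the list alone.

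The groups, comparisons, tests, gene lists, most alternatives and the rule for named genes were set before the data were examined. The rule took, per comparison, the 10 largest rises and the 10 largest falls among called genes with a group mean of at least 1 CPM, up to 4 members with the smallest adjusted p of each list that passed, and 17 fixed genes. A subset of these genes is named in the text, and the others are given as counts and ranges. Genes outside the rule are identified as such. Coordinates come from the GRCm38.p6 annotation, matched by symbol for 244 of the 245 genes the rule gave.

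Other settings chosen at that stage were DESeq2 1.42.0, edgeR 4.0.16 with RLE factors, no filter on low values, only the compared groups in the fit, limma-voom, limma-voom with the title letter as a random effect, edgeR with 1 surrogate variable (sva 3.50.0), and leaving out each library in turn. Those that need counts were run on the recovered reads. Added after the data were seen were edgeR with TMM, DESeq2 with no filter, pseudocounts of 0.5 and 8, the library means of the choroid plexus and thalamus lists as covariates, a fit without the 8 libraries whose thalamus list mean was more than 0.5 above the average, and a fit without library 17. On simulated counts with known changes in the ECT comparison on the control diet, the test recovered 44% of genes changed 1.25-fold, 66% at 1.5-fold, 88% at 2-fold and 98% at 4-fold, over 15225 genes, with 6 unchanged genes called. The simulated genes varied independently, without shared tissue carry-over. In all 154 were called there, which makes the adjusted threshold easier to pass. Such shares therefore do not tell what was missed in a real comparison with few or no called genes. Analyses used R 4.3.3.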

Results

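The series measured hippocampal gene expression in male C57BL/6 mice aged 4 to 8 months. Stressed mice went through chronic unpredictable stress (CUS), a 5-week schedule of changing mild stressors, after 3 weeks on their diet. The PLX diet contained a compound that the labels name PLX5562 and list as an inhibitor of the CSF1 receptor, the kinase on which microglia depend for survival. Stressed mice then had sham treatment or ECT, in which a brief current induces a seizure, over 2.5 weeks at 3 sessions a week. The design asks whether stress, ECT and loss of microglia change the hippocampal transcriptome, and whether the ECT response differs between the diets. Libraries held 14.97 M to 20.12 M reads assigned to genes, and between 17290 and 17751 genes had a value above 0.

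Markers of tissue next to the hippocampus varied widely within every group. Ttr, the transthyretin gene expressed mainly by choroid plexus in brain, ran from 904 to 78579 normalized read counts, an 86.9-fold range. Tcf7l2, a transcription factor abundant in thalamus, ran from 92.9 to 1259. In a principal component analysis of the log2 values, component 1 held 24.7% of the variance. Its absolute correlation was 0.880 with the thalamus list mean and 0.829 with the choroid plexus list mean. Component 2 held 16.3%, with an absolute correlation of 0.929 with the microglia core list mean. The thalamus and habenula list passed no test in any comparison, with medians between -0.42 and 0.15 on the log2 scale, while the choroid plexus list differed between some groups and its values stand with those comparisons. Library 17, from the PLX sham group, had 2.90% of its reads on the ribosomal RNA gene Rn45s, against 0.598 to 1.005% in the others.

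**Figure D1:**
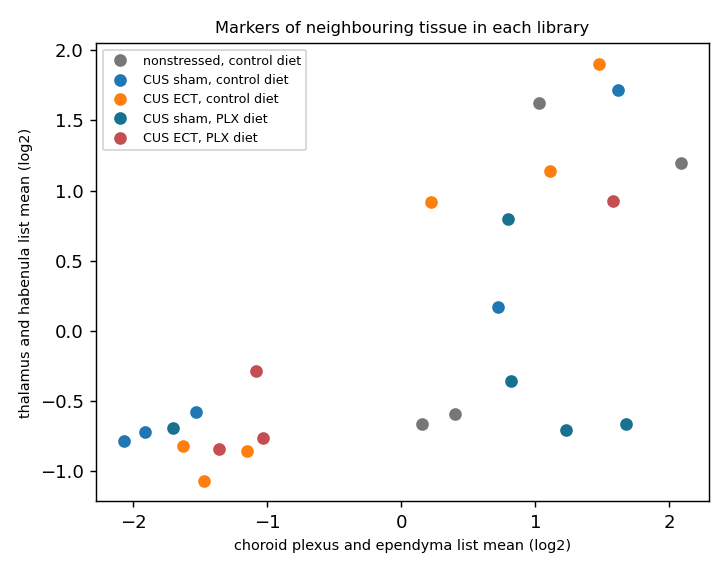
Each point is 1 library, placed by the mean log2 value of the choroid plexus and ependyma list (horizontal) and of the thalamus and habenula list (vertical), relative to the mean of all 24 libraries, and coloured by group. The 8 libraries highest on the vertical axis lie at 0.797 or above and the other 16 at 0.170 or below, and each group has libraries in both sets.

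Among sham-treated mice, genes of microglia were lower on the PLX diet. P2ry12, a purinergic receptor of homeostatic microglia (chromosome 3, 59216271 to 59262985), was at 89.6 ± 21.2 on the PLX diet (n = 5) and 645 ± 56.2 on the control diet (n = 5), so that 13.9% of its level remained (log2 fold change -2.86, SE 0.13, adjusted p = 6.29e-13). Csf1r, the receptor targeted by the diet (chromosome 18, 61105572 to 61131139), fell from 1780.4 ± 167 to 304 ± 94.3. Cx3cr1, the fractalkine receptor, fell from 794 ± 62.1 to 133 ± 36.6, and Tmem119, a microglial surface protein, from 401 ± 37.2 to 71.4 ± 25.6. All 34 members of the microglia core list fell (median -2.30), including Trem2, a lipid-sensing receptor, Gpr34, P2ry13 and Aif1, which codes for the marker IBA1. The list passed with the preset correlation (adjusted p = 1.17e-146) and with an estimated one (adjusted p = 5.24e-05).

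Some genes of other immune groups were lower too. In bulk tissue, loss of microglia and lower expression per cell cannot be told apart for these genes, nor for the interferon genes and B2m below. That limit holds among ECT mice too. In the border and perivascular macrophage list, 4 of 7 tested members fell and 3 did not pass, with 6 lower when adjusted over the list alone (median -2.26, adjusted p = 3.68e-15, and adjusted p = 0.000249 with an estimated correlation). Mrc1, the mannose receptor, fell from 30.6 ± 10.0 to 2.16 ± 0.844, and Stab1, a scavenger receptor, from 197 ± 13.6 to 38.3 ± 5.04. Of 9 tested immune checkpoint genes, 4 fell and 5 did not pass, with the same 4 lower when adjusted over the list alone. These were Havcr2 (TIM-3), Cd86, Lgals9 (galectin-9) and Lag3, an inhibitory receptor that binds MHC class II (chromosome 6, 124904359 to 124912434), which fell from 158 ± 36.8 to 40.4 ± 11.1 (log2 -1.94, SE 0.28, adjusted p = 6.08e-05). The checkpoint list had a median of -0.17 (-0.06 without library 21) and a mean of -0.75 (adjusted p = 2.04e-06, and adjusted p = 0.0343 with an estimated correlation, which became 0.201 with the choroid plexus and thalamus means as covariates). In the inflammatory cytokine list 3 of 12 fell, 5 when adjusted over the list alone (median -0.60, and -0.33 without library 21, adjusted p = 1.47e-07, and adjusted p = 0.00662 with an estimated correlation). Nlrp3, an inflammasome sensor, fell from 24.1 ± 4.52 to 3.98 ± 2.02, and Tgfb1 from 159 ± 16.4 to 51.9 ± 9.13. Il1a fell by 1.52, a call lost without any of libraries 7, 8, 11, 18, 19 and 21 (adjusted p 0.0703 to 0.127), with the title letter as a random effect (adjusted p = 0.114) and without the 8 libraries richest in thalamic transcripts (adjusted p = 0.0547).

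Interferon response genes were lower as a list (median -0.49, 3 of 23 fell and 20 did not pass, 5 lower adjusted over the list alone, adjusted p = 9.83e-10), but the list did not pass with an estimated correlation (adjusted p = 0.285 with an estimated correlation). Trim30a fell by 1.34, Usp18, which removes the ubiquitin-like modifier ISG15, by 1.39 and Xaf1 by 0.49 on the log2 scale. The Usp18 call was lost without any of libraries 7, 8, 10, 20 and 21 (adjusted p 0.0506 to 0.113), and the Xaf1 call without any of 7, 8, 10, 11, 17, 19, 20 and 21 (0.0558 to 0.176). With only these groups in the fit Trim30a (adjusted p = 0.118), Usp18 (0.0930), Xaf1 (0.164) and Il1a (0.0623) were lost, and with the tissue covariates Trim30a (0.150), Usp18 (0.196) and Il1a (0.0672). Xaf1 was also lost with the title letter (adjusted p = 0.0930) and without the 8 libraries richest in thalamic transcripts (adjusted p = 0.217). B2m, the light chain of MHC class I, fell from 2767 ± 422 to 1834 ± 323, a call lost with only these groups in the fit (adjusted p = 0.0623). In the disease-associated microglia list 3 of 16 fell, among them Ctsd, a lysosomal protease, from 5529 ± 392 to 4351 ± 287. That list had a median of -0.09 (-0.17 without library 9, -0.16 without 20, -0.06 without 7 and -0.04 without 19) and a mean of -0.37 (adjusted p = 0.00212, and adjusted p = 0.212 with an estimated correlation). The ligands of the CSF1 receptor did not pass: Il34 was at 557 ± 57.7 on the PLX diet and 588 ± 26.0 on the control diet (adjusted p = 0.869), and Csf1 at 707 ± 69.6 and 714 ± 72.2 (adjusted p = 0.974).

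In all, 283 genes were called between the diets in sham mice, 270 lower and 13 higher on the PLX diet. The 10 largest falls spanned -3.31 to -2.69 and the 10 largest rises 0.19 to 0.61 on the log2 scale. Snx25, a sorting nexin, rose from 729 ± 35.0 to 874 ± 35.0, and Flrt2, a cell adhesion protein, from 752 ± 24.6 to 916 ± 62.0. Both calls held in every alternative run, but narrowly, with adjusted p up to 0.0490 for Snx25 and 0.0492 for Flrt2. Emilin1, the largest rise, lost its call in 17 of 23 alternatives and Ahr in 16 of 23. Lrrk2, a kinase gene, rose by 0.41, a call lost without any of libraries 7, 8, 17, 18 and 20 (adjusted p 0.0712 to 0.138), and Rab13 by 0.59, lost without any of 7, 10, 17 and 18 (0.0556 to 0.0887). Lrrk2 was also lost with the title letter (adjusted p = 0.0735), with the tissue covariates (0.129) and without the 8 libraries richest in thalamic transcripts (0.0754), and Rab13 with the title letter (0.0664), with only these groups in the fit (0.0577) and without the 8 libraries (0.132). The count of higher genes was 3 without library 7, 4 without 8, 6 without 17, 5 without 18, 20 without 9 and 22 without 21, while that of lower genes stayed between 234 and 277. DESeq2 gave 31 higher genes, edgeR with 1 surrogate variable 46, the tissue covariates 30 and limma-voom with the title letter 3. Gfap, the intermediate filament of astrocytes, was at 8659 ± 794 on the PLX diet and 6479 ± 680.5 on the control diet (adjusted p = 0.318, and 0.0116 with only these groups in the fit, where it was called). Of the 17 fixed genes 6 were called, all microglial genes or Lag3, and 11 were not. The choroid plexus list was higher on the PLX diet in these libraries (median 1.23, adjusted p = 0.000771, and adjusted p = 0.514 with an estimated correlation). Meningeal fibroblast genes were higher too, with 11 of 11 positive (median 0.61, and 0.33 without library 17, adjusted p = 4.74e-05, and adjusted p = 0.359 with an estimated correlation), as were neocortex genes, with 9 of 10 positive (median 0.31, and 0.21 without library 18, adjusted p = 0.00363, and adjusted p = 0.411 with an estimated correlation).

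**Figure D2:**
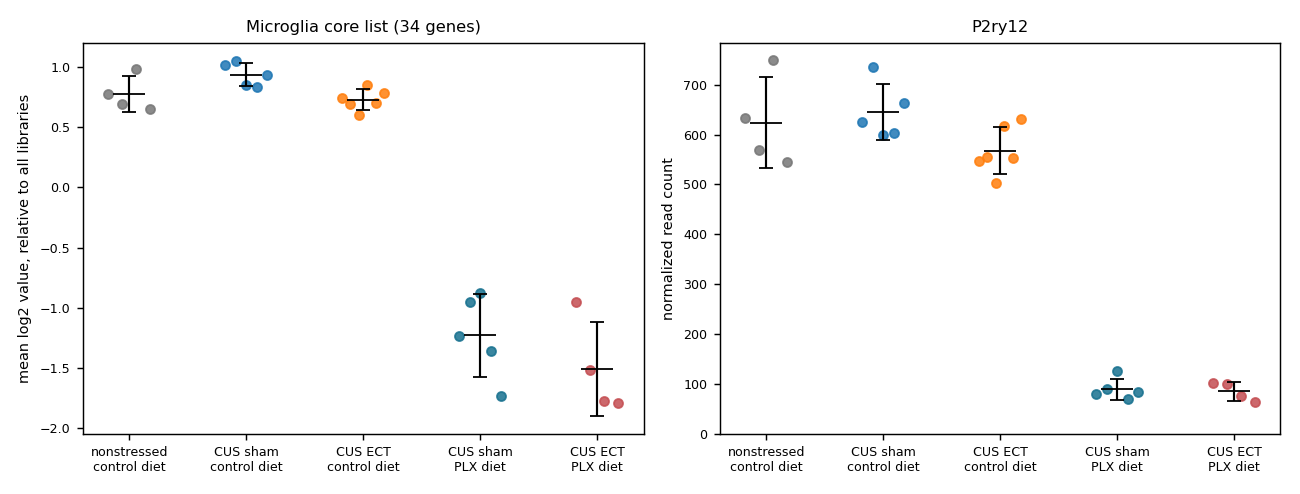
Left, the mean log2 value of the 34 genes of the microglia core list in each library, relative to all 24 libraries, and right, the normalized read count of P2ry12. Points are libraries, horizontal bars are group means and error bars are SD (n = 4 to 6), and the PLX libraries lie below every control-diet library in both panels, with P2ry12 at 63.9 to 125 against 504 to 749.

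Among ECT-treated mice, microglial genes were also lower on the PLX diet. P2ry12 was at 85.6 ± 19.1 on the PLX diet (n = 4) and 568 ± 47.9 on the control diet (n = 6), a log2 fold change of -2.74 (SE 0.14, adjusted p = 2.53e-12). Csf1r fell from 1613 ± 109.7 to 230.1 ± 53.2. Crybb1, a crystallin expressed by microglia, fell from 65.1 ± 15.9 to 2.13 ± 2.01, and Abcc3, a transporter, from 40.3 ± 10.2 to 2.68 ± 2.14. All 34 members of the microglia core list fell (median -2.32, adjusted p = 5.94e-136, and adjusted p = 8.89e-05 with an estimated correlation), as did 6 of 7 border macrophage genes (median -2.54, adjusted p = 1.62e-14, and adjusted p = 0.000327 with an estimated correlation). Of 9 checkpoint genes 4 fell and 5 did not pass, with 5 lower and 1 higher adjusted over the list alone (median -0.14, mean -0.84, adjusted p = 1.18e-06, and adjusted p = 0.0395 with an estimated correlation, 0.0801 with the tissue covariates). Lag3 fell from 86.2 ± 35.1 to 26.8 ± 12.1 (log2 -1.64, SE 0.29, adjusted p = 0.000817), Cd86 from 27.8 ± 5.85 to 3.63 ± 2.00 and Havcr2 from 53.4 ± 6.70 to 9.80 ± 5.71. Inflammatory cytokine genes had 3 of 12 lower, 4 adjusted over the list alone, a median of -0.06 and a mean of -0.49 (adjusted p = 0.00344, and adjusted p = 0.182 with an estimated correlation). Their median was between -0.22 and -0.10 without any of libraries 1, 3, 5, 6, 12, 13 and 14, lowest without 12.

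Genes of mature dentate granule cells were higher on the PLX diet after ECT. All 12 members had a positive fold change (median 0.35); 2 rose and 10 did not pass, with 6 higher when adjusted over the list alone (adjusted p = 4.42e-08, and adjusted p = 0.229 with an estimated correlation). Tdo2, tryptophan 2,3-dioxygenase, rose from 92.2 ± 25.8 to 155 ± 28.4 (log2 0.77, SE 0.15, adjusted p = 0.00195). Plk5, a polo-like kinase, rose from 562 ± 209.7 to 954 ± 157 (log2 0.83, SE 0.19, adjusted p = 0.0187), a call lost without library 4 (adjusted p = 0.0534) or 12 (adjusted p = 0.106). Among the 10 largest rises, which spanned 0.78 to 1.22, were Ntf3, which codes for neurotrophin 3 (111 ± 35.3 to 199.5 ± 35.0), Wnt9a, a secreted Wnt ligand (157 ± 20.8 to 270.0 ± 42.4), and Cyp26b1, which degrades retinoic acid (169 ± 55.0 to 294 ± 45.2). The Cyp26b1 call was lost without library 15 (adjusted p = 0.0591), that of Nhlh1, a transcription factor, without 12 (adjusted p = 0.129), that of Mafa without any of 1, 4, 13, 14 and 15 (0.0524 to 0.0966), and that of Sla2 without any of 2, 4, 12, 14 and 15 (0.0647 to 0.125). Sox11, a transcription factor of immature neurons, was lower on the PLX diet, at 288 ± 13.6 against 389 ± 46.2 (log2 -0.42, SE 0.09, adjusted p = 0.00516). Lists of neighbouring tissue differed beside the granule genes. Meningeal fibroblast genes had 10 of 11 positive fold changes (median 0.40, and 0.23 without library 6 or 0.18 without 12, adjusted p = 0.0142, and adjusted p = 0.660 with an estimated correlation). Striatum genes had 0 of 9 positive, but the list did not pass (median -0.19, adjusted p = 0.0869). Control-diet libraries 4 and 6 had the lowest granule list means of these 10 libraries (-0.712 and -0.409) and the highest means of the striatum list (0.623 and 0.858) and the neocortex list (0.6002 and 0.298). The neurogenesis list had 1 of 20 members lower, 2 adjusted over the list alone (median -0.15, adjusted p = 0.0417, and adjusted p = 0.229 with an estimated correlation). It no longer passed without the 8 libraries richest in thalamic transcripts (median -0.05, adjusted p = 0.213) or with the tissue covariates (adjusted p = 0.0504), and the median was -0.10 without library 3 and -0.09 without 12.

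In all, 350 genes were called, 283 lower and 67 higher on the PLX diet. The count of higher genes was 34 without library 4, 13 without 12, 21 without 15 and 101 without 1, and the total was 227 without library 15. Without the 8 libraries richest in thalamic transcripts, a fit added after the data were seen, 195 genes were lower and 4 higher, and Plk5 (adjusted p = 0.294), Ntf3 (0.0856), Cyp26b1 (0.234), Nhlh1 (0.230), Mafa (0.188), Sla2 (0.481) and Sox11 (0.143) no longer passed. That fit left 3 libraries in each of these groups. With only these 2 groups in the fit, 213 were lower and 16 higher, and Tdo2 (adjusted p = 0.0890), Plk5 (0.222), Ntf3 (0.0948), Cyp26b1 (0.145), Nhlh1 (0.0968), Mafa (0.0738) and Sla2 (0.0627) were lost. With the title letter as a random effect in limma-voom, 235 genes were called, 23 of them higher, and Nhlh1 (adjusted p = 0.0510), Mafa (0.0567) and Sla2 (0.116) were lost. DESeq2 gave 105 higher genes and edgeR with 1 surrogate variable 101. Chaperone genes were lower as a list (median -0.32, 0 of 17 called, 11 lower adjusted over the list alone, median -0.49 without library 14, adjusted p = 2.96e-09, and adjusted p = 0.246 with an estimated correlation).

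Of the genes lower on the PLX diet, 221 were called in both sham and ECT mice, from 270 and 283, where 5.02 would be shared by independent lists. The 2 comparisons share no library. None of the 13 and 67 higher genes was shared, where independent lists would share 0.0572. Across the 15225 genes, the fold changes correlated at r = 0.609, and genes are not independent replicates.

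In mice on the control diet, ECT was compared with sham. Sox11 (chromosome 12, 27334268 to 27342718) rose from 271 ± 11.3 in sham mice (n = 5) to 389 ± 46.2 after ECT (n = 6), a log2 fold change of 0.51 (SE 0.08, adjusted p = 0.0319). It was the only gene limma called, with 1048 genes at an unadjusted p below 0.05 where chance gives 761 on average. The fold change lay between 0.46 and 0.55 under every alternative, but the call was lost without any of libraries 1, 2, 5, 7, 8, 9, 10 and 11 (adjusted p 0.0821 to 0.207), with only the compared groups (adjusted p = 0.107), with the title letter (0.156), with the tissue covariates (0.0617), without the 8 libraries richest in thalamic transcripts (adjusted p = 0.999974), and without library 17 of the PLX sham group (adjusted p = 0.0506). edgeR called 1 gene, limma-voom 2 and DESeq2 10, and limma called 3 without library 3 and 4 without library 6. Csf2rb2, a cytokine receptor subunit called by limma-voom and DESeq2, was at 37.1 ± 8.5 after ECT and 67.96 ± 4.46 in sham mice (adjusted p = 0.0706 by limma), and was singled out after its values were seen.

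Genes of neurogenesis and immature neurons rose as a list after ECT (median 0.13, 16 of 20 positive, adjusted p = 0.000282, and adjusted p = 0.0317 with an estimated correlation, which became 0.0691 with the tissue covariates). Of its members 1 rose and 19 did not pass, and 1 was higher adjusted over the list alone. Sox4 was at 326 ± 27.2 and 281 ± 18.4 (adjusted p = 0.524), Nes, the progenitor filament nestin, at 109 ± 23.4 and 83.8 ± 11.9 (adjusted p = 0.648), and Dcx, doublecortin, at 310.3 ± 68.1 and 285 ± 36.4 (adjusted p = 0.951). Monoamine receptor genes also rose as a list (median 0.15, and 0.24 without library 3, 14 of 16 positive, adjusted p = 0.000506, and adjusted p = 0.0266 with an estimated correlation). No member was called and 1 passed when adjusted over the list alone: Drd1, the dopamine D1 receptor, which also belongs to the striatum list, at 109 ± 25.4 and 73.6 ± 11.3 (adjusted p = 0.378 over all genes). The striatum list was higher in the same comparison, with 8 of 9 positive (median 0.26, adjusted p = 0.00154, and adjusted p = 0.276 with an estimated correlation), and libraries 4 and 6 of the ECT group had the highest means, 0.623 and 0.858. Htr5b, a serotonin receptor, was at 138 ± 18.4 and 111 ± 18.5 (adjusted p = 0.693).

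All 17 chaperone genes had a positive fold change after ECT (median 0.34). limma called none over all genes and 16 passed when adjusted over the list alone (adjusted p = 6.09e-21, and adjusted p = 0.0519 with an estimated correlation). Hsph1, a cytosolic HSP110 chaperone, was at 5570.3 ± 358 after ECT and 4499.8 ± 184 in sham mice (log2 0.31, SE 0.07, adjusted p = 0.299 by limma and 0.0471 by DESeq2), and Pdia4, a disulfide isomerase of the endoplasmic reticulum, at 919 ± 244 and 638 ± 70.9. Immediate early genes had 21 of 23 positive fold changes (median 0.25, 0 called, adjusted p = 1.50e-07, and adjusted p = 0.276 with an estimated correlation). Fos was at 272 ± 176 and 113 ± 55.7 (adjusted p = 0.715) and Egr1 at 3422 ± 1091 and 2441 ± 455 (adjusted p = 0.715). Without the 8 libraries richest in thalamic transcripts the immediate early list no longer passed (median 0.08, adjusted p = 0.180), and its median was 0.16 without library 4.

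Immune genes had lower means after ECT on the control diet. All 34 microglia core genes had a negative fold change (median -0.20, 0 called, adjusted p = 4.31e-07, and adjusted p = 0.510 with an estimated correlation), for example Trem2 at 182 ± 27.2 against 248 ± 29.5. All 12 antigen presentation genes (median -0.41, 2 lower adjusted over the list alone, adjusted p = 2.90e-07, and adjusted p = 0.276 with an estimated correlation) and all 23 interferon response genes (median -0.29, adjusted p = 2.04e-08, and adjusted p = 0.359 with an estimated correlation) were negative too. B2m was at 2093 ± 138 after ECT and 2767 ± 422 in sham mice (adjusted p = 0.456). Lag3 was at 86.2 ± 35.1 after ECT and 158 ± 36.8 in sham mice (log2 -0.93, SE 0.27, unadjusted p = 0.0022, adjusted p = 0.458). Dentate granule genes had 11 of 12 negative fold changes (median -0.13, 2 lower adjusted over the list alone, adjusted p = 0.001, and adjusted p = 0.510 with an estimated correlation). That median was -0.02 without library 4, -0.08 without 6, -0.19 without 3 and -0.21 without 9.

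**Figure D3:**
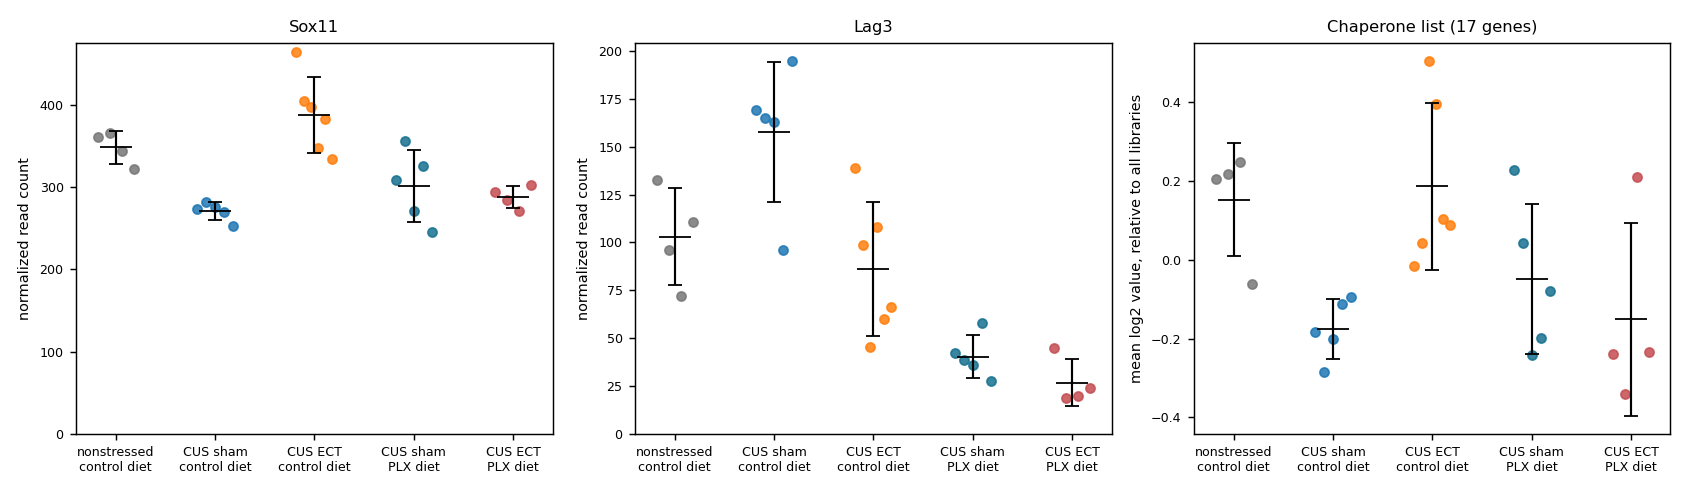
Normalized read counts of Sox11 and Lag3, and the mean log2 value of the 17 chaperone genes relative to all 24 libraries, by group. Points are libraries, horizontal bars are group means and error bars are SD (n = 4 to 6), and on the control diet the ECT libraries lie at 334 to 464 for Sox11 and the sham libraries at 253 to 283, while for Lag3 the ranges of 45.3 to 139 and 96.0 to 195 overlap.

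On the PLX diet, no gene passed the test between ECT and sham mice. limma called 0 genes, with 388 at an unadjusted p below 0.05 where chance gives 761 on average, and edgeR and DESeq2 called 0. Lag3 was at 26.8 ± 12.1 after ECT (n = 4) and 40.4 ± 11.1 in sham mice (n = 5, log2 -0.62, SE 0.30, adjusted p = 0.999). The remaining microglial transcripts had lower means after ECT: 30 of 34 microglia core genes were negative (median -0.32, and -0.20 without library 14 or 15, 3 lower adjusted over the list alone, adjusted p = 2.40e-12, and adjusted p = 0.637 with an estimated correlation). Irf8, a transcription factor of myeloid cells, was at 24.3 ± 15.8 and 38.8 ± 6.72, and Cd33, a sialic acid receptor, at 15.5 ± 5.69 and 26.6 ± 10.6 (both adjusted p = 0.999). Without library 12, 2 genes were called, Irf8 (adjusted p = 0.00822) and Adgre1, the macrophage marker F4/80 (adjusted p = 0.0196), the latter chosen after its values were seen. Dentate granule genes had 10 of 12 positive fold changes (median 0.15, adjusted p = 0.0203, and adjusted p = 0.834 with an estimated correlation). They no longer passed without the 8 libraries richest in thalamic transcripts (median 0.06, adjusted p = 0.366) or with the tissue covariates (adjusted p = 0.0615), and the median was 0.04 without library 12 and 0.10 without 18. The choroid plexus list was lower after ECT here (median -0.86, and -1.46 without library 12 or -1.34 without 19, adjusted p = 0.00112, and adjusted p = 0.810 with an estimated correlation). Meningeal fibroblasts had 10 of 11 negative fold changes (median -0.34, and -0.08 without library 17, -0.22 without 18 or -0.56 without 19, adjusted p = 0.00976, and adjusted p = 0.810 with an estimated correlation). Neocortex genes had 10 of 10 negative (median -0.23, and -0.35 without library 21, adjusted p = 0.00137, and adjusted p = 0.637 with an estimated correlation).

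The difference between the ECT effects on the 2 diets was tested as an interaction. limma, edgeR and DESeq2 called 0 genes, with 1043 at an unadjusted p below 0.05 by limma. The ECT effect on Sox11 was 0.51 on the control diet and -0.05 on the PLX diet, a difference of -0.57 (SE 0.12, unadjusted p = 0.000116, adjusted p = 0.626). For Lag3 the difference was 0.31 (SE 0.40, adjusted p = 0.912), but 0.04 without library 12, 0.14 without 3, 0.18 without 21, 0.46 without 1, 0.47 without 10 and -0.05 without the 8 libraries richest in thalamic transcripts. It was 0.47 with the tissue covariates. For Plk5 the difference was 0.88 (SE 0.27, adjusted p = 0.644), for Hsph1 -0.35 (SE 0.10, adjusted p = 0.626) and for Rsad2, an antiviral interferon-induced gene, 0.94 (SE 0.37, adjusted p = 0.689). Chaperone genes differed as a list, with all 17 negative (median -0.46, 12 passing adjusted over the list alone, adjusted p = 1.04e-15, and adjusted p = 0.135 with an estimated correlation), and the median was -0.26 without the 8 libraries richest in thalamic transcripts. In all, 12 of 33 lists passed with the preset correlation but 0 with an estimated one, among them choroid plexus (median -1.33, adjusted p = 0.00083, and adjusted p = 0.644 with an estimated correlation). On simulated counts for this contrast, with independent genes and 135 called in all, the test recovered 60% of genes with a 1.5-fold and 80% with a 2-fold difference. Those shares do not carry over to the real contrast with 0 called genes. Across the 15225 genes the ECT effects of the 2 diets correlated at r = -0.0424 (Spearman -0.168). Groups with no effect gave a central range of -0.462 to 0.485 over 1000 simulations, with the extremes on both sides left out. The correlation was 0.0474 without library 4, 0.0101 without 7 and 0.000316 without 21, and -0.235 over the 11605 genes with a mean of at least 5 CPM.

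In mice on the control diet, stressed sham mice were compared with nonstressed mice. The labels give no sham treatment for the nonstressed mice, so stress and sham treatment cannot be told apart here. The stressed sham libraries held 15.16 M to 16.23 M reads and the nonstressed ones 16.55 M to 17.69 M. limma called 0 genes, with 989 at an unadjusted p below 0.05 where chance gives 761 on average. edgeR called 0 and DESeq2 called 1, Top1, which codes for DNA topoisomerase I, at 1609 ± 92.4 in stressed (n = 5) and 1909 ± 49.5 in nonstressed mice (n = 4, adjusted p = 0.144 by limma and 0.000419 by DESeq2). limma called Top1 without library 10 (adjusted p = 0.0424), and called Fancd2, a DNA repair gene, without library 25 (adjusted p = 0.00845). Both genes were singled out after their values were seen. Chaperone genes were lower in stressed mice, with all 17 negative (median -0.34, 6 lower adjusted over the list alone, adjusted p = 1.03e-12, and adjusted p = 0.503 with an estimated correlation). Hspa5, the BiP chaperone of the endoplasmic reticulum (chromosome 2, 34772090 to 34776529), was at 3099.7 ± 362 and 4572 ± 718, Sdf2l1 at 157 ± 18.8 and 253 ± 54.5, and Creld2 at 228 ± 27.1 and 323 ± 50.0 (each adjusted p = 0.759).

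Interferon response genes were higher in stressed mice, with 22 of 23 positive (median 0.34, 0 called, adjusted p = 6.34e-08, and adjusted p = 0.503 with an estimated correlation). Irf7, a regulator of interferon production, was at 116 ± 25.1 and 68.0 ± 11.0, Ifit1 at 137 ± 27.4 and 83.7 ± 11.4, and Isg15 at 47.5 ± 11.1 and 28.4 ± 2.97 (each adjusted p = 0.759). Microglia core genes had 29 of 34 positive fold changes (median 0.18, adjusted p = 0.000355, and adjusted p = 0.662 with an estimated correlation), with Ctss, cathepsin S, at 1315 ± 126 and 988 ± 14.6. Lag3 was at 158 ± 36.8 in stressed and 103 ± 25.4 in nonstressed mice (log2 0.61, SE 0.30, unadjusted p = 0.0535, adjusted p = 0.759), and Sox11 at 271 ± 11.3 and 349 ± 20.0 (log2 -0.36, SE 0.09, adjusted p = 0.562). The choroid plexus list was lower in stressed mice, with all 16 members negative (median -1.35, adjusted p = 1.52e-07, and adjusted p = 0.503 with an estimated correlation). Meningeal fibroblasts had 9 of 11 negative (median -0.32, adjusted p = 0.0111, and adjusted p = 0.662 with an estimated correlation), and no longer passed with the tissue covariates (adjusted p = 0.150). On simulated counts for this contrast, with independent genes and 156 called in all, the test recovered 76% of genes changed 1.5-fold and 86% of genes changed 2-fold. Those shares do not carry over to the real stress comparison, where limma called no gene.

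Stressed mice given ECT on the control diet were compared with nonstressed mice. The same 6 ECT libraries enter the ECT comparison on the control diet, the PLX comparison in ECT mice and the interaction. Results that recur among these comparisons, such as those of granule genes and Sox11, are therefore not independent. limma called 0 genes, with 1118 at an unadjusted p below 0.05, edgeR 0 and DESeq2 20. Without library 3, limma called 11. Dentate granule genes were lower in the stressed and ECT-treated mice, with all 12 negative (median -0.23, and -0.15 without library 4, 3 lower adjusted over the list alone, adjusted p = 5.34e-07, and adjusted p = 0.394 with an estimated correlation). Tdo2 was at 92.2 ± 25.8 after stress and ECT (n = 6) and 141 ± 7.62 in nonstressed mice (n = 4, log2 -0.65, SE 0.15, adjusted p = 0.246, 0.0182 without library 3 and 0.0490 by DESeq2). Plk5 was at 562 ± 209.7 and 907 ± 150.2 (adjusted p = 0.350), and Lct at 1285 ± 304 and 1803 ± 258 (adjusted p = 0.542). GABAergic interneuron genes had 13 of 13 positive fold changes (median 0.20, adjusted p = 1.72e-05, and adjusted p = 0.394 with an estimated correlation), with Slc32a1, the vesicular GABA transporter, at 1651 ± 289.6 and 1305 ± 141. Without the 8 libraries richest in thalamic transcripts the interneuron median was 0.06 (adjusted p = 0.0356), and without library 23 it was 0.12. Lists of neighbouring tissue moved in the same comparison: choroid plexus had 15 of 16 negative fold changes (median -1.06, and -0.67 without library 22, adjusted p = 0.000787, and adjusted p = 0.798 with an estimated correlation). Meningeal fibroblasts had 10 of 11 negative (median -0.50, adjusted p = 0.000787, and adjusted p = 0.591 with an estimated correlation). Striatum genes had 9 of 9 positive (median 0.27, and 0.16 without library 6 or 0.42 without 1, adjusted p = 0.00868, and adjusted p = 0.591 with an estimated correlation). H2-Aa, an MHC class II chain, was at 26.0 ± 19.5 and 49.9 ± 17.8 (adjusted p = 0.664), and Sox11 at 389 ± 46.2 and 349 ± 20.0 (adjusted p = 0.761).

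The stress and ECT effects on the control diet were set against each other to ask whether ECT moved genes opposite to stress. Across 15225 genes they correlated at r = -0.499, with a covariance of -0.0172. Both effects use the same 5 sham libraries with opposite sign. Simulated groups with no effect gave a median r of -0.507 (central range -0.805 to -0.0580, extremes left out) and a mean covariance of -0.0180. The observed covariance differed from the simulated one by 0.000823. When the sham libraries were divided so that each effect used its own part, the 20 arrangements gave r between -0.206 and 0.394 (median -0.0690), negative in 14 and positive in 6.

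**Figure D4:**
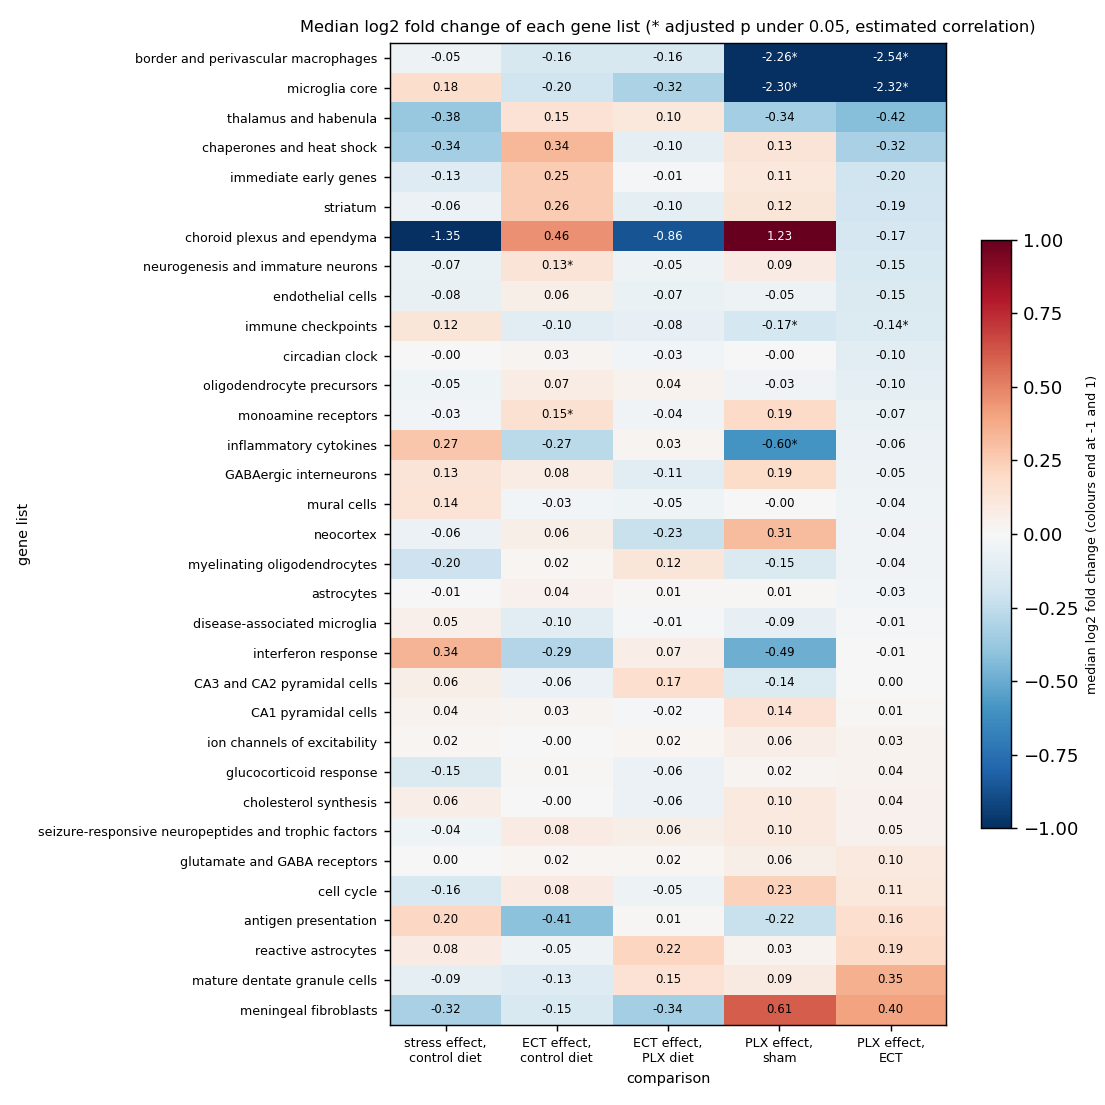
Median log2 fold change of each of the 33 tested gene lists (vertical) in 5 comparisons (horizontal), with red for higher and blue for lower in the first-named condition and a star where the list passed with an estimated correlation. The microglia core list lies at -2.30 and -2.32 in the PLX comparisons, and the stars stand in those and in the ECT comparison on the control diet.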

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

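The list tests of the difference between the ECT effects and the test of interferon genes with microglia as a covariate were set before the result was seen. The other tests that weigh an explanation in this part were chosen only after the result was seen.

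In 16 of 260 combinations of a group and a measure, 1 library lay far from the others of its group, where chance gives about 13. Library 17 (PLX sham) had 2.90% of its reads on Rn45s and a thalamus list mean of 0.797. Choroid plexus list means were -1.70 in library 19 (PLX sham) and 1.58 in library 12 (PLX ECT). In nonstressed mice, library 25 stood apart in inflammatory cytokines (-0.0689) and chaperones (-0.0612), library 24 in monoamine receptors (-0.193) and Npy (1281 normalized read counts), and library 22 in Calb1 (1713). In control-diet sham mice, library 9 stood apart in reactive astrocytes (-0.209), cholesterol synthesis (0.0466) and Dcx (347). In control-diet ECT mice, library 3 stood apart in CA1 genes (-0.614) and library 5 in Gfap (13359). In PLX ECT mice, library 12 stood apart in cholesterol synthesis (-0.144) and library 13 in Bdnf (688).

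The ECT effect differed between the diets for 12 lists with the preset correlation, and for none of them with an estimated one. The median differences, PLX minus control diet, were 0.463 for antigen presentation, 0.450 for interferon response, 0.328 for dentate granule cells and 0.267 for CA3 and CA2 cells. They were -1.33 for choroid plexus, -0.375 for neocortex, -0.357 for striatum, -0.345 for immediate early genes, -0.236 for monoamine receptors, -0.190 for GABAergic interneurons, -0.164 for neurogenesis and -0.459 for chaperones. Without the 8 libraries richest in thalamic transcripts the immediate early genes (-0.0420, adjusted p = 0.794) and neocortex (-0.165, adjusted p = 0.0662) no longer passed, and the differences were -0.256 for chaperones, 0.166 for granule cells and -0.0811 for interneurons. With the tissue covariates CA3 and CA2 cells (adjusted p = 0.0702) no longer passed. Neither did choroid plexus (adjusted p = 0.949), but its own list mean is a covariate there, so that loss was fixed in advance. Leaving out library 12 gave 0.163 for interferon response, 0.275 for antigen presentation and -0.227 for immediate early genes. Interferon response was 0.288 without library 21, granule cells 0.202 without 4, CA3 and CA2 cells 0.151 without 18 and neurogenesis -0.109 without 5.

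Chaperone genes were lower in stressed sham mice and higher after ECT on the control diet, though neither list test passed with an estimated correlation. Both differences use the same sham libraries with opposite sign, so they are not independent. The ECT difference of the list mean was 0.361 (SE 0.111). Tissue carried over at dissection is argued against as the whole cause, since the difference was 0.341 (SE 0.103) with the choroid plexus and thalamus means as covariates and 0.349 (SE 0.119) with the striatum and neocortex means. Body temperature or time of day at death may account for it: with the mean of the cold-inducible genes Cirbp and Rbm3 as covariate it was 0.0561 (SE 0.0719). The stress difference of the chaperone list mean was -0.328 (SE 0.122), and -0.0988 (SE 0.0717) with that covariate. The Cirbp and Rbm3 mean itself was lower after ECT (-0.339, SE 0.106) and higher in stressed sham than in nonstressed mice (0.254, SE 0.117). Across 24 libraries, as deviations from group means, the measures correlated at r = -0.860 (permutation p = 1e-04) and rho = -0.832 (permutation p = 8e-05), 1 relation tested, and r was -0.801 without libraries 14 and 4. That explanation stays open beside ECT itself, because Cirbp and Rbm3 might respond to ECT and neither temperature nor hour is given in the sources used here.

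Dentate granule cell genes were higher on the PLX diet among ECT mice, with a difference of the list mean of 0.384 (SE 0.124), and 0.0775 (SE 0.121) among sham mice. The list test among ECT mice did not pass with an estimated correlation. Granule differences in other comparisons with control-diet ECT mice use the same ECT libraries, so they are not independent of this one. A rise of every gene through the scaling could not be tested: the median log2 fold change of all genes was 0.00269, but the size factors hold this median near 0 in every comparison (-0.00539 to 0.00269). Library 4 alone is argued against by a difference of 0.283 (SE 0.099) without it. Library 6, with the next lowest granule mean among the control-diet ECT libraries (-0.409), was not left out together with library 4. Both together therefore stay open as a cause. Tissue carried over is argued against as the whole cause by 0.382 (SE 0.132) with the choroid plexus and thalamus means as covariates and 0.292 (SE 0.0944) with the striatum and neocortex means, the latter leaving part of it open. A larger share of granule cells in the dissected tissue was not tested, and an effect of diet after ECT stays open as a hypothesis.

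Interferon response genes were higher in stressed sham mice than in nonstressed mice, with a difference of 0.379 (SE 0.143) over the 15 control-diet libraries, where the fit to all 24 libraries gave an SE of 0.1999. As a list they did not pass with an estimated correlation. A single library is argued against: 4 of the 5 sham libraries lay above every nonstressed library (at most 0.0982), and the lowest difference on leaving out each sham library in turn was 0.304 (SE 0.141, control-diet libraries), without library 7. That criterion was revised after the values were seen, and a stricter one was not met, since 0.304 less 1 SE is 0.164, under 50% of the full difference (0.1897). More microglia could account for part of it: the difference was 0.259 (SE 0.165) with the microglia mean as covariate, too wide a spread to decide. Stress itself, which these groups do not separate from sham treatment, stays open, as untested.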

How the results depend on the processing

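The fits with TMM, with other pseudocounts, with tissue covariates, without filter in DESeq2, and without the 8 thalamic libraries or library 17 were chosen after seeing the data. Of 104 gene results 54 were called, 33 of them in every setting and 21 lost in at least 1, and none of the called ones changed sign. The interaction gave 0 genes in every setting by limma, edgeR and DESeq2 (1043 at an unadjusted p below 0.05 by limma). Where a value moved, the cause was not tested.

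With DESeq2, with and without the filter, the stress comparison gave 1 and 1 genes, ECT on the control diet 10 and 11, and stress plus ECT against nonstressed mice 20 and 21. For ECT on the control diet limma-voom gave 2, and 0 were called with only the compared groups (limma), the title letter (limma-voom), tissue covariates, the 8 libraries out or library 17 out, against 1048 at an unadjusted p below 0.05 by limma. The PLX comparison in ECT mice gave 229 with only the compared groups and 199 with the 8 libraries out. Leaving out each library gave 0 to 1 genes for stress, 0 to 4 for ECT on the control diet, 0 to 2 for ECT on the PLX diet, 237 to 286 and 227 to 387 for PLX in sham and ECT mice, and 0 to 11 for stress plus ECT.

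Over all 33 tested lists, camera with the estimated correlation, fry in one direction and fry in either direction called 2, 3 and 2 for ECT on the control diet, 4, 7 and 7 for PLX in sham mice, 3, 7 and 6 for PLX in ECT mice, and 0, 0 and 0 in the other 4 comparisons. The exact permutation test of list means gave 0 in each of the 6 comparisons of 2 groups. Groups this small limit how low its p can go, so a single list could not pass on its own when adjusted over 33 lists. The 0 therefore says little about the lists. For the microglia core list the permutation p was 0.00794 in sham mice (252 arrangements) and 0.00476 in ECT mice (210 arrangements), the smallest those arrangements allow, and 0.0655 and 0.0524 when adjusted over the lists. Il34 in the PLX sham comparison was 0.04 (0.0437) with tissue covariates, Csf1 in the PLX sham comparison ranged from -0.0712 without library 9 to 0.0482 without library 19, with 0.0319 without library 7, and the Lag3 interaction -0.0533 with the 8 libraries out. The correlation of ECT effects between diets was -0.235 (Spearman -0.282) over the 11605 genes with a mean of at least 5 CPM. On leaving out each library it ranged from -0.110 to 0.0474 (0.0474 without library 4, 0.0101 without 7, 0.000316 without 21), and could not be given over called genes, since 1 gene was called in either diet. The stress and ECT correlation with sham libraries split, each value the mean of both assignments of the parts, was -0.118 (7 and 8), -0.190 (7 and 9), -0.0891 (7 and 10), 0.266 (7 and 11), 0.0321 (8 and 9), -0.0967 (8 and 10), -0.0970 (8 and 11), -0.0225 (9 and 10), -0.0422 (9 and 11) and -0.0215 (10 and 11).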

Other observations

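All tests in this part that compare the called counts with other splits were chosen only after the result was seen.

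Reactive astrocyte genes were higher on the PLX diet among ECT mice (median 0.19, and 0.29 without library 3 or 0.28 without 14, 2 of 19 rose and 17 did not pass, 3 higher adjusted over the list alone, adjusted p = 0.0265, and adjusted p = 0.707 with an estimated correlation). C4b, a complement component, rose from 1063 ± 173 (n = 6) to 1719 ± 353 (n = 4), a call lost without library 12 (adjusted p = 0.0773) or 13 (adjusted p = 0.0719) and without the 8 libraries richest in thalamic transcripts (log2 0.57, adjusted p = 0.477). Aspg, an asparaginase, rose from 27.3 ± 4.21 to 43.9 ± 8.82, a call lost without any of libraries 2, 3, 4, 12, 13, 14 and 15 (adjusted p 0.0554 to 0.239), with the title letter as a random effect (adjusted p = 0.114), with only the compared groups (adjusted p = 0.119) and with no filter (adjusted p = 0.0521). Without the 8 libraries its log2 fold change of 0.66 became 0.34 (adjusted p = 0.923). Gfap was at 10685 ± 1342 and 7799 ± 2806 (adjusted p = 0.131), and was called without library 5 (log2 0.67, adjusted p = 0.000192). Per2, a component of the circadian clock, fell from 1045 ± 80.5 to 796 ± 67.4 (log2 -0.39, adjusted p = 0.00793), a call lost without library 15 (adjusted p = 0.0562) and without the 8 libraries (adjusted p = 0.114), while the circadian list did not pass (adjusted p = 0.0989).

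Genes of myelinating oligodendrocytes had 15 of 16 negative fold changes in stressed sham against nonstressed mice (median -0.20, 0 called by limma, adjusted p = 0.00734, and adjusted p = 0.662 with an estimated correlation). That list no longer passed with the tissue covariates (median -0.05, adjusted p = 0.621) or without the 8 libraries richest in thalamic transcripts (median -0.13, adjusted p = 0.168), and its median was -0.13 without library 9, -0.11 without 24 and -0.32 without 25. On the PLX diet, 16 of 16 were positive after ECT (median 0.12, adjusted p = 0.0121, and adjusted p = 0.925 with an estimated correlation), but the median turned negative without library 13 (-0.00516) or 19 (-0.0238) and was 0.21 to 0.23 without 12, 15 or 21. Glucocorticoid response genes had 17 of 18 negative fold changes in stressed sham mice (median -0.15, and -0.03 without library 25, -0.23 without 23 or -0.29 without 24, adjusted p = 0.000365, and adjusted p = 0.503 with an estimated correlation), with Pdk4, a kinase that restrains pyruvate oxidation, at 131 ± 16.9 (n = 5) and 167 ± 12.1 (n = 4, adjusted p = 0.759 by limma). The glucocorticoid list median was -0.08 with the tissue covariates and -0.27 without the 8 libraries. Seizure-responsive neuropeptides and trophic factors did not pass after ECT on the control diet (median 0.08, adjusted p = 0.0799). Bdnf, a neurotrophin, was at 828 ± 215 after ECT and 721 ± 48.1 in sham mice (adjusted p = 0.878). Cell cycle genes were higher on the PLX diet among sham mice (median 0.23, and 0.43 without library 20, 1 of 17 higher adjusted over the list alone, adjusted p = 0.000217, and adjusted p = 0.106 with an estimated correlation).

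Each count of called genes was set against 100 splits of the same libraries, the real one included. For the PLX comparison in sham mice, 1 of 100 splits gave as many as 283, the real one, and the highest other gave 0. That share of 0.01 is the lowest that 100 splits can give, so chance is made unlikely but not excluded. The splits also treat libraries that share a title letter as independent. For the PLX comparison in ECT mice, 2 of 100 gave as many as 350. The highest other split called 1207 genes, several times the real count, which points to a structure of the samples: it set libraries 3, 4, 6 and 13 against the rest. The parts differed in the list means of thalamus by 0.763, striatum by 0.671, microglia by 0.576 and choroid plexus by 0.503. The striatum means of those 4 libraries (0.221, 0.623, 0.858 and 0.217) were above those of the other 6 (at most -0.00883), while the thalamus means were -0.822 in library 6 and -0.290 in 13, against 0.921 in library 2 and 0.924 in 12. For ECT on the control diet, 11 of 100 splits gave at least the 1 gene called, with a highest other of 34, so chance cannot be excluded. For the 4 comparisons with 0 called genes by limma, any split calls at least as many, so that the 100 of 100 splits decide nothing about chance. The highest others were 15 for stress, 25 for ECT on the PLX diet, 224 for the interaction and 74 for stress plus ECT. Their unadjusted counts below 0.05 were 989, 388, 1043 and 1118.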
